A study of Mus musculus with 55 samples.

How the data were processed

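RNA sequencing was done on 55 libraries of adipose tissue from male C57BL/6NRj mice. Per the labels' protocols, the tissue was cryosectioned, chosen areas were collected by laser capture microdissection, total RNA was isolated with a micro-scale column kit, and about 2 ng of RNA per sample went into a full-length library with the SMART-Seq2 protocol. The labels and the series text give the depot, the treatment (corticosterone, GC, or placebo, Ctrl), the housing temperature (22 °C or 13 °C), the age of 10 weeks and the 4 weeks of treatment. Groups were taken from these labels, and replicate numbers from the titles. The labels do not say which libraries share an animal, when samples were collected, or how areas were chosen for capture.

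The deposited values are raw read counts per gene, in 1 table per depot with 31933 Ensembl genes. Per the submitters' processing notes, reads were checked with FastQC, aligned to mm10 with GSNAP and counted with featureCounts (version 1.6.3). The annotation release, the strand setting and the handling of multi-mapping reads are not given in the sources used here. No column was left unused, and the values were whole numbers with totals that differed between libraries. Gene IDs were matched to symbols, positions and biotypes of GENCODE M21 on GRCm38, the assembly also named mm10, and 17153, 20164 and 18993 of the tested genes of iBAT, goWAT and scWAT had a name there. The SMART-Seq2 protocol marks no strand, so reads of a gene and of an overlapping or antisense gene cannot be told apart. Counts of near-identical genes are uncertain in the same way, among them Hspa1a, Hspa1b, the Mup genes, the alpha and beta haemoglobin genes and mitochondrial genes with nuclear copies.

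Each depot was fitted on its own. With edgeR 4.0.16 in R 4.3.3, genes were kept by filterByExpr with its defaults (at least 10 counts at the median library size in as many libraries as the smallest group, and 15 counts in all), which left 17163 genes in iBAT, 20175 in goWAT and 19003 in scWAT. Counts were scaled with TMM factors, dispersions were estimated robustly, and 1 mean per group was fitted with the robust quasi-likelihood method. The biological coefficient of variation was 50.5% in iBAT, 49.99% in goWAT and 47.8% in scWAT. The 5 contrasts per depot were GC against Ctrl at 22 °C and at 13 °C, 13 °C against 22 °C in Ctrl and in GC, and the interaction, which is the GC effect at 13 °C minus that at 22 °C. For the depots, 1 fit over the 55 libraries tested whether the GC effect differed between the 3 depots, by a quasi-likelihood F-test at each temperature over 22245 genes. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. Standard errors of log2 fold changes were derived from the F statistic, and CPM are counts scaled to the TMM-adjusted library size. The design without a replicate block, the tests, the gene lists and the naming rule were fixed before the data were examined.

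The 26 gene lists for pathways of adipose tissue and for other cell types were written from general knowledge. They were tested in each of the 15 comparisons within a depot with camera in limma 3.58.1 on voom values, with the preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists of a comparison. Lists with fewer than 5 tested members were left out. Camera with an estimated correlation and fry were run beside it. Counts of list members that rose or fell are from the edgeR test over all genes and from the same p-values adjusted over the list alone. Some genes stand in more than 1 list, such as Per1 in those of receptor targets and of the clock.

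Genes named in the text follow a rule. For each comparison within a depot, it takes the 6 largest rises and 6 largest falls among genes past the threshold with a mean of at least 3 log2 CPM, a proper symbol and no overlap between the groups (for the interaction 4 and 4, by adjusted p, without the condition on overlap). It takes the 8 smallest adjusted p for each test between depots, up to 4 members of each called list in its direction with up to 2 in the other, and a fixed set of genes that includes Fkbp5, Ucp1, Dio2, Lep and Fasn. The text names fewer than the rule allows.

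The code was tested on simulated data, drawn from the means and library sizes of the real libraries with 200 genes changed by a known fold. Of genes changed 4-fold, 46% to 61% were recovered in the 12 comparisons between groups and 18%, 41% and 32% in the interactions of iBAT, goWAT and scWAT. Of genes changed 2-fold, 0% to 16% were recovered over the 15 comparisons. There were 0 to 7 false calls per comparison and none with the wrong sign. For the test between depots at 22 °C, 24% and 2% were recovered. Changes of 2-fold were thus mostly below what these group sizes and this spread can call, and a gene that was not called is not shown to be unchanged. Depth per library ran from 8622178 to 56450653 counts in scWAT, which had the widest range, with medians of 19692103, 36440481 and 26669500 in iBAT, goWAT and scWAT. Reads carry no molecular identifiers, so the spread between libraries, not counting error, sets the precision.

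Alternatives fixed in advance were RLE scaling, no filter, DESeq2 1.42.0, limma with voom and library weights, a replicate block, only the compared groups in the fit, leaving out libraries of low quality (log10 total or number of detected genes more than 3 median absolute deviations below the median of the depot) and leaving out each library of the compared groups. For the tests between depots DESeq2's likelihood-ratio test was used, since the contrast has more than 1 degree of freedom. Chosen after seeing the data were fits without libraries rich in markers of skeletal muscle, macrophages, mesothelium or brown fat (mean log2 CPM of the list more than 3 median absolute deviations above the median of the depot), without the goWAT libraries over 100 CPM of Crisp1, and the tests between depots without each library. Other splits of the same libraries were fitted for each count, up to 100 per comparison and 40 for each test between depots. Figures were drawn with matplotlib 3.10.9.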

Results

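The series asks how the temperature at which mice are housed changes what glucocorticoids do to different fat depots. Male C57BL/6NRj mice were given corticosterone (GC), the main glucocorticoid of mice, or placebo (Ctrl) in drinking water for 4 weeks, at 22 °C (RT) or at 13 °C (CT). RNA from laser-captured areas of interscapular brown fat (iBAT), gonadal white fat (goWAT) and subcutaneous white fat (scWAT) gave 55 sequencing libraries in 12 groups. The groups held 3 Ctrl_RT, 5 GC_RT, 5 Ctrl_CT and 5 GC_CT libraries in iBAT, 4, 5, 5 and 5 in goWAT, and 4, 5, 5 and 4 in scWAT. Total gene counts ran from 14043773 to 35790654 per library in iBAT, 12310822 to 53121372 in goWAT and 8622178 to 56450653 in scWAT. Within groups, log2 CPM (counts scaled to library size) of 2 libraries correlated at 0.850 to 0.969 over all 101 pairs, and none of these pairs held identical counts. The labels tie no library to an animal. The p-values therefore measure the spread between these libraries, and some libraries, across depots too, can come from 1 animal.

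Transcripts of other cell types were unevenly spread over the libraries. In scWAT, GC_RT replicates 2 and 3 had mean log2 CPM of 8.22 and 8.17 over 18 macrophage markers, where the other 16 libraries lay at 3.65 to 6.18. The same pair had 4.36 and 4.02 over 18 cell cycle genes, against -0.23 to 1.68 in the rest. Skeletal muscle markers reached 7.27 in scWAT GC_RT replicate 2, 5.52 in goWAT GC_RT replicate 2 and 5.36 in iBAT GC_CT replicate 4. Krt18, an epithelial keratin, was at 27.4 CPM in scWAT Ctrl_CT replicate 3 and at 21.7, 94.7 and 98.9 CPM in GC_CT replicates 3, 4 and 5, while the other 14 scWAT libraries lay at 0 to 0.538. The brown fat gene Ucp1 stood at 473 and 594 CPM in goWAT GC_RT replicate 1 and GC_CT replicate 1, against 0.0243 to 23.1 in the other 17 goWAT libraries. Crisp1, a gene of the epididymis chosen after its values were seen, was at 1288, 513 and 3559 CPM in goWAT GC_RT replicate 5 and Ctrl_CT replicates 1 and 4, and at 0 to 48.01 in the rest.

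**Figure D1:**
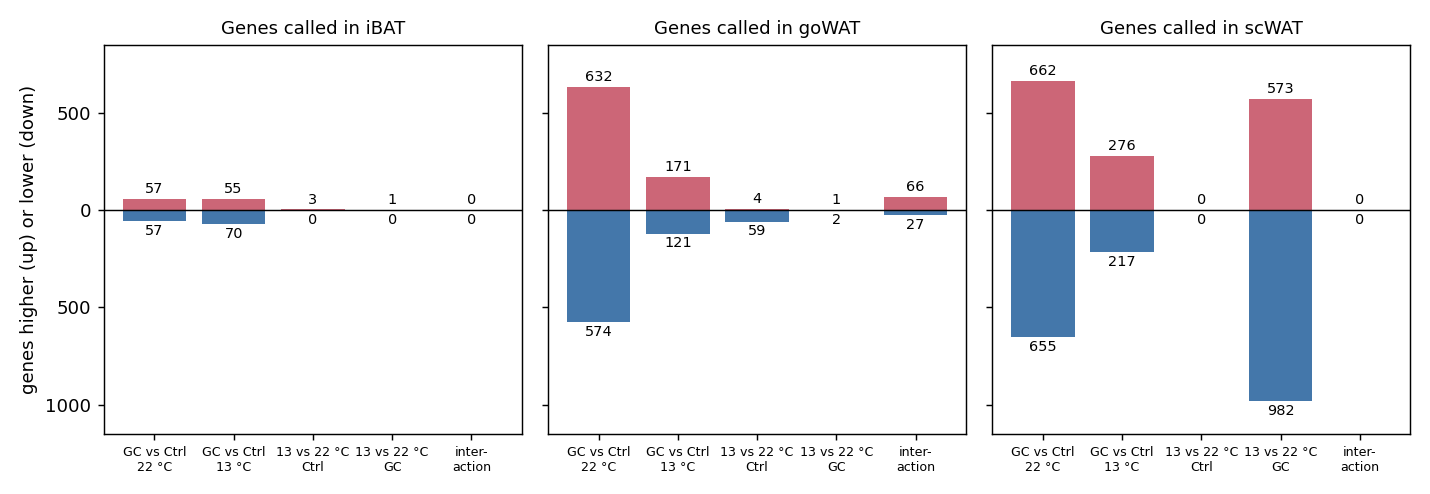
Number of genes called higher (upward bars) and lower (downward bars) in each comparison within a depot, by edgeR's quasi-likelihood test at an adjusted p under 0.05. The bars run from 0 on a linear scale, and the tallest stand in scWAT for corticosterone at 22 °C and for 13 °C against 22 °C under corticosterone.

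What corticosterone did to brown fat at room temperature was asked with 5 GC_RT and 3 Ctrl_RT libraries of iBAT. Hspa1a, an inducible heat shock protein 70 gene, stood at 250.1 ± 125 CPM with corticosterone and at 9.44 ± 3.65 without (mean ± SD), a rise of 4.73 ± 0.59 on the log2 scale (± SE here and in all fold changes). Cyp2b10, a cytochrome P450, rose by 4.62 ± 0.51, Lrrc32, which holds latent TGF-beta at the cell surface, by 3.46 ± 0.69, and Tnfrsf12a, the receptor of the cytokine TWEAK, by 2.996 ± 0.58. Among the genes that fell were the transcription factors Irf4 (-3.55 ± 0.60) and Klf15 (-3.32 ± 0.40), the matrix proteoglycan gene Lum (-3.09 ± 0.55), Rasd1, a Ras-like gene named for its response to dexamethasone (-2.60 ± 0.45), and the vitamin transporter Slc5a6 (-2.58 ± 0.40). Of 18 circadian clock genes, 2 rose and 6 fell (6 and 8 when adjusted over the list alone): Arntl, which encodes BMAL1, and Cry1 rose by 3.65 ± 0.62 and 2.73 ± 0.44, and Dbp, Per1 and Per3 fell (log2 fold changes -3.23 ± 0.48, -2.09 ± 0.31 and -1.99 ± 0.31; camera adjusted p = 0.0181, and adjusted p = 0.382 with an estimated correlation). Among 23 known targets of the glucocorticoid receptor, 0 rose and 2 fell (4 and 8 when adjusted over the list alone), Per1 and Nfkbia, the NF-kappaB inhibitor, being those that fell (camera adjusted p = 0.0191, and adjusted p = 0.489 with an estimated correlation). Nfkbia changed by -1.86 ± 0.32 and Fkbp5, a co-chaperone of the receptor, by 1.66 ± 0.56 (adjusted p = 0.209 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). No gene of triglyceride uptake and synthesis passed over all genes, and adjusted over the list alone 1 of 20 rose and 8 fell (camera adjusted p = 3.43e-05, and adjusted p = 0.257 with an estimated correlation). Camera placed the white adipocyte, extracellular matrix, lymphocyte, skeletal muscle and erythrocyte lists lower and the fatty acid oxidation, oxidative phosphorylation and immediate early lists higher (adjusted p = 1.19e-06 to 0.0224). With an estimated correlation these had adjusted p = 0.286 to 0.640. Ucp1, the uncoupling protein of brown fat, stood at 6032 ± 6382 CPM in Ctrl_RT and 3602 ± 754 in GC_RT (-0.74 ± 0.51, edgeR adjusted p = 0.642), and its log2 fold change was positive with library weights (0.40) or without Ctrl_RT replicate 3 (0.58).

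In all, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 57 genes higher and 57 lower among 17163 tested, with adjusted p = 0.000129 to 0.0172 for the genes named here that passed. Libraries did not overlap for 7.57% of tested genes (3.57% by chance). The count was 26 without Ctrl_RT replicate 1 and GC_RT replicate 5, both rich in macrophage markers, 65 with only these groups in the fit, 394 with DESeq2 and 971 with limma and library weights. Hspa1a (ENSMUSG00000091971, protein coding, chromosome 17, 34969190 to 34972156 on GRCm38) has a near-identical neighbour, Hspa1b, so its counts can hold reads of both.

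At 13 °C the same question in iBAT rested on 5 GC_CT and 5 Ctrl_CT libraries. Cd164l2 rose by 3.32 ± 0.40, Hspa1a by 2.93 ± 0.43, Lox, the collagen cross-linking lysyl oxidase, by 1.87 ± 0.29 and Phlda1 by 1.89 ± 0.42. Irf4 fell (-3.96 ± 0.58), as did the deubiquitinase gene Usp2 (-3.13 ± 0.40) and Rasd1 (-2.78 ± 0.42). Of 18 clock genes, 2 rose and 7 fell (2 and 8 when adjusted over the list alone): Arntl and Npas2 rose by 3.28 ± 0.50 and 3.39 ± 0.63, and Dbp and Per1 fell (-3.96 ± 0.47 and -2.87 ± 0.30). This list was lower by camera with both the preset correlation (adjusted p = 1.53e-06) and an estimated one (adjusted p = 0.0342). Of 23 receptor targets, 0 rose and 5 fell (2 and 7 when adjusted over the list alone): besides Per1, Tsc22d3, which encodes the anti-inflammatory protein GILZ, fell (-2.21 ± 0.29), as did Nfkbia (-1.85 ± 0.29) and Sgk1, a kinase induced by serum and glucocorticoids (-1.58 ± 0.24; camera adjusted p = 2.16e-05, and adjusted p = 0.166 with an estimated correlation). The triglyceride list was lower with Gpat4, a glycerol-3-phosphate acyltransferase, as the gene that fell among 20 (-0.99 ± 0.23; 2 fell and 0 rose when adjusted over the list alone; camera adjusted p = 0.0201, and adjusted p = 0.527 with an estimated correlation). The test called 55 genes higher and 70 lower among 17163 tested (named genes at edgeR adjusted p = 5.37e-05 to 0.0477). Libraries did not overlap for 2.65% of tested genes (0.794% by chance). Without Ctrl_CT replicate 4 and GC_CT replicate 4, both rich in muscle transcripts (their setting also left out Ctrl_RT replicate 3), the count was 54. DESeq2 called 385 and limma with library weights 263.

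Housing at 13 °C against 22 °C in placebo mice changed few single genes of iBAT (5 and 3 libraries). Cyp2b10 rose by 2.79 ± 0.46, from 9.002 ± 4.62 to 62.6 ± 34.1 CPM, Retreg1, a receptor for autophagy of the endoplasmic reticulum, by 2.11 ± 0.30, and BC028528 by 2.20 ± 0.37 (adjusted p = 0.0110 to 0.0342 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). These 3 genes, none of which overlapped between groups, passed of 17163 tested. Gene lists moved in both directions without a single member past the threshold over all genes. The fatty acid oxidation list was higher, with 3 of 21 genes that rose and 0 that fell when adjusted over the list alone (median log2 fold change 0.36; camera adjusted p = 1.55e-06, and adjusted p = 0.354 with an estimated correlation). Camera also placed the oxidative phosphorylation, mitochondrially encoded, thermogenic and clock lists higher (medians 0.27, 0.56, 0.26 and 0.25; adjusted p = 1.17e-06 to 0.000347, and adjusted p = 0.288 to 0.398 with an estimated correlation). The extracellular matrix, white adipocyte, macrophage, endothelial, skeletal muscle and erythrocyte lists were lower (medians -0.91, -0.60, -0.87, -0.30, -0.68 and -1.38; adjusted p = 4.25e-07 to 0.0186, and adjusted p = 0.335 to 0.584 with an estimated correlation). Without Ctrl_RT replicate 1, highest of these 8 libraries on macrophage markers (mean log2 CPM 4.32), their median was -0.14 (camera adjusted p = 0.407). Without Ctrl_RT replicate 3 or Ctrl_CT replicate 4, both at 4.48 on muscle markers, the muscle median was 0.18 or -3.23. Mean log2 CPM in Ctrl_RT ran from 6.54 to 8.42 on white adipocyte genes and 5.22 to 6.58 on thermogenic ones. In Ctrl_CT these were 6.45 to 7.73 and 5.83 to 6.73. White fat in Ctrl_RT areas was not tested as a source, here or in other comparisons with this group. The count was 0 without Ctrl_RT replicate 1 and GC_RT replicate 5.

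Under corticosterone, 13 °C against 22 °C (5 and 5 iBAT libraries) raised Elovl3, a fatty acid elongase of brown fat, by 3.36 ± 0.45, from 49.8 ± 15.9 to 511 ± 453 CPM. It was the 1 gene called of 17163 (adjusted p = 0.00317 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), with no overlap between the groups. Macrophage and cell cycle genes were lower as lists: adjusted over the list alone, 11 of 18 and 10 of 17 fell (median log2 fold changes -2.22 and -2.42; camera adjusted p = 0.00158 and 0.00117, and adjusted p = 0.777 with an estimated correlation). Without GC_RT replicate 5, rich in both (6.44 and 2.69 mean log2 CPM), the medians were -0.52 and -1.35, and neither list was called (camera adjusted p = 0.351 and 0.0940). The immediate early and extracellular matrix lists were lower too, and the oxidative phosphorylation, mitochondrially encoded and skeletal muscle lists higher (camera adjusted p = 0.000161 to 0.00616, and adjusted p = 0.777 with an estimated correlation). The muscle list was not called without GC_CT replicate 4 (camera adjusted p = 0.182). DESeq2 called 388 genes, and limma with library weights 4.

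Whether the corticosterone effect itself differed between temperatures was asked with the interaction over all 18 iBAT libraries, positive where the effect was more upward at 13 °C. edgeR called 0 of 17163 genes, with 1098 at an unadjusted p under 0.05 and a smallest adjusted p of 0.126. DESeq2 called 9 and limma with library weights 1. As lists, white adipocyte, skeletal muscle and erythrocyte genes had positive median interactions (0.77, 3.15 and 0.98) and fatty acid oxidation, clock and Schwann cell genes negative ones (-0.25, -0.40 and -0.88), at camera adjusted p = 1.47e-06 to 0.00845, and adjusted p = 0.124 to 0.610 with an estimated correlation. The muscle median was 1.94 without the muscle-rich Ctrl_RT 3, Ctrl_CT 4 and GC_CT 4 together, 1.95, 5.21 and 0.73 without each, and 7.15 without GC_RT 3. Without Ctrl_RT 2 the white adipocyte and erythrocyte lists had camera adjusted p = 0.0888.

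In goWAT at 22 °C, corticosterone (5 libraries against 4) changed many genes. Hspb7, a small heat shock protein gene, stood at 1.74 ± 0.352 CPM in Ctrl_RT and 403 ± 208 CPM in GC_RT, a rise of 7.86 ± 0.69. Sfrp5, a secreted Wnt inhibitor, rose by 4.22 ± 0.85, the metallothionein Mt2 by 4.14 ± 0.49, the p21 cell cycle inhibitor Cdkn1a by 3.60 ± 0.44, leptin (Lep) by 2.85 ± 0.39 and Fkbp5 by 1.98 ± 0.38. Irf4 fell (-3.39 ± 0.79), together with Slc5a6 (-2.87 ± 0.26) and the lactate receptor Hcar1 (-2.65 ± 0.43). Of 20 triglyceride genes, 0 rose and 6 fell (0 and 6 when adjusted over the list alone). Of 21 lipogenesis genes, 0 rose and 3 fell (1 and 4 when adjusted over the list alone). Acsl1, which activates fatty acids, changed by -1.62 ± 0.33, the lipogenic transcription factor Srebf1 by -1.45 ± 0.30 and the citrate carrier Slc25a1 by -2.07 ± 0.54. For these lists camera gave adjusted p = 0.0162 and 9.46e-05, and adjusted p = 0.586 with an estimated correlation. Of 18 lipolysis genes, 1 rose and 6 fell (2 and 6 when adjusted over the list alone): the lipid droplet gene Plin1 fell (-1.33 ± 0.24) and G0s2, an inhibitor of the lipase ATGL, rose by 1.35 ± 0.34 (camera adjusted p = 0.0455, and adjusted p = 0.495 with an estimated correlation). Of 13 mitochondrially encoded transcripts, 4 rose and 0 fell (11 and 0 when adjusted over the list alone), mt-Co2 by 2.25 ± 0.44 (camera adjusted p = 1.72e-09, and adjusted p = 0.386 with an estimated correlation). Mitochondrial genes held 6.77% ± 2.003 of all counts in GC_RT and 2.999% ± 1.21 in Ctrl_RT (mean ± SD).

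Matrix, clock and lymphocyte genes moved as well. Of 28 extracellular matrix genes, 7 rose and 1 fell (13 and 3 when adjusted over the list alone), with Lox and Sparc up by 1.94 ± 0.33 and 1.93 ± 0.32 and Lum down (-1.31 ± 0.31; camera adjusted p = 9.46e-05, and adjusted p = 0.544 with an estimated correlation). Of 18 clock genes, 3 rose and 7 fell (4 and 10 when adjusted over the list alone): Arntl rose by 3.06 ± 0.41, and Dbp and Nr1d2, which encodes REV-ERB beta, fell (-4.47 ± 0.45 and -2.84 ± 0.31; camera adjusted p = 0.000148, and adjusted p = 0.158 with an estimated correlation). Of 18 lymphocyte markers, 0 rose and 5 fell (1 and 8 when adjusted over the list alone), among them Cd74, the invariant chain of MHC class II (-1.60 ± 0.33), and Cd4 (-3.40 ± 0.91; camera adjusted p = 0.000164, and adjusted p = 0.355 with an estimated correlation). Of 16 endothelial markers, 0 rose and 2 fell (0 and 6 when adjusted over the list alone), with the VEGF receptor Kdr at -0.85 ± 0.25. The endothelial, fatty acid oxidation and cell cycle lists were lower (camera adjusted p = 4.37e-05, 0.0112 and 0.0112, and adjusted p = 0.495 to 0.704 with an estimated correlation). edgeR called 632 genes higher and 574 lower among 20175 tested, the named genes that passed at edgeR adjusted p = 1.4e-06 to 0.0485. Libraries did not overlap for 8.32% of tested genes (1.59% by chance). The count was 709 without GC_RT replicates 2 and 4, the libraries of low quality, 2113 without GC_RT replicate 1 and GC_CT replicate 1, rich in brown fat transcripts, 655 with these groups alone in the fit and 2204 with DESeq2.

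At 13 °C (5 and 5 goWAT libraries) corticosterone raised Hspb7 by 4.16 ± 0.52, Mthfd2, a mitochondrial enzyme of folate metabolism, by 2.83 ± 0.51, the phosphatase gene Dusp10 by 2.49 ± 0.36 and Lep by 1.58 ± 0.34. Irf4 fell (-3.34 ± 0.75), as did the efflux transporter Abcg2 (-2.68 ± 0.59) and the protease gene Pcsk4 (-2.32 ± 0.37). Of 18 clock genes, 3 rose and 8 fell (4 and 9 when adjusted over the list alone). Arntl and Npas2 rose by 3.53 ± 0.39 and 4.22 ± 0.64, and Dbp (-3.89 ± 0.43), Ciart (-4.95 ± 0.53), Per1 (-2.47 ± 0.25) and Per2 (-2.42 ± 0.38) fell. The clock list was lower by camera with the preset correlation (adjusted p = 7.26e-06) and with an estimated one (adjusted p = 0.0428). Of 16 endothelial markers, 0 rose and 1 fell (1 and 7 when adjusted over the list alone), with VE-cadherin (Cdh5) at -1.07 ± 0.26. Of 20 triglyceride genes, 0 rose and 1 fell (0 and 4 when adjusted over the list alone), with Gpihbp1, which carries lipoprotein lipase to the capillary wall, at -1.27 ± 0.31. In the cell cycle list Rrm2 fell (-1.78 ± 0.45). Camera placed these 3 lists lower, with the mitochondrially encoded and erythrocyte lists (adjusted p = 8.51e-05 to 0.0168, and adjusted p = 0.711 to 0.746 with an estimated correlation). The comparison gave 171 genes higher and 121 lower among 20175 tested (named genes at edgeR adjusted p = 3.02e-05 to 0.0491). Libraries did not overlap for 4.79% of tested genes (0.794% by chance). The count was 91 without the 3 libraries over 100 CPM of Crisp1, 500 with these groups alone, 897 with DESeq2 and 2202 with limma and library weights.

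Placebo mice at 13 °C against 22 °C (5 and 4 goWAT libraries) showed more lower than higher genes. Adcyap1r1, the receptor of the neuropeptide PACAP, rose by 1.95 ± 0.37. Scand1 fell (-2.66 ± 0.34), with Trim14 (-2.38 ± 0.42), the ubiquitin ligase gene Rnf187 (-2.29 ± 0.24), Inafm1 (-2.25 ± 0.27) and Bloc1s4, a part of a complex for lysosome-related organelles (-2.14 ± 0.33). Plin1, which coats lipid droplets, went from 955 ± 248 to 275 ± 42.8 CPM (-1.80 ± 0.24) and was the single gene of 18 lipolysis genes past the threshold, also when adjusted over the list alone (camera adjusted p = 0.0429, and adjusted p = 0.525 with an estimated correlation). Glucocorticoid receptor targets, mitochondrially encoded transcripts and mesothelium markers were higher as lists and erythrocyte genes lower (medians 0.40, 0.44, 0.92 and -1.12; camera adjusted p = 0.000603 to 0.0219, and adjusted p = 0.525 to 0.688 with an estimated correlation). Mesothelium and keratin genes were highest in Ctrl_CT replicate 4 (Krt18 at 60.2 CPM), which also led in Crisp1. The test called 4 genes higher and 59 lower among 20175 tested (named genes at edgeR adjusted p = 3.02e-05 to 0.0159). Libraries did not overlap for 3.55% of tested genes (1.59% by chance). The count was 12 without the 3 libraries rich in Crisp1, 11 without Ctrl_RT replicate 4, 113 with these groups alone, 196 with DESeq2 and 186 with limma and library weights.

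Under corticosterone, goWAT at 13 °C against 22 °C (5 and 5 libraries) differed in 3 of 20175 genes, 1 higher and 2 lower. Prelp, a matrix proteoglycan, fell (-1.81 ± 0.31), as did the mitochondrial serine tRNA gene mt-Ts1 (-2.36 ± 0.40; adjusted p = 0.0387 and 0.0387 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The gene that rose, Rassf6, has a low level (from 0.295 to 2.58 CPM, log2 fold change 3.17 ± 0.49, edgeR adjusted p = 0.0287) and was named after its values were seen. All 3 were without overlap between groups. Of 13 protein-coding mitochondrial transcripts, 0 passed over all genes and 12 fell when adjusted over the list alone (median -1.41; camera adjusted p = 1.65e-16, and adjusted p = 0.290 with an estimated correlation). Mitochondrial genes held 3.47% ± 2.03 of counts in GC_CT (mean ± SD), against 6.77% in GC_RT. Receptor targets, matrix and erythrocyte genes were lower and lymphocyte and fatty acid oxidation genes higher as lists (camera adjusted p = 2.46e-07 to 0.0106, and adjusted p = 0.293 to 0.711 with an estimated correlation). The count was 304 without GC_RT replicate 1, which carried the brown fat transcripts, 0 without GC_RT replicates 2 and 4, and 418 with DESeq2.

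The interaction in goWAT (19 libraries) asked which corticosterone effects differed between 13 °C and 22 °C. Hspb7 rose with corticosterone at both temperatures, by less at 13 °C, with an interaction of -3.70 ± 0.71. The interaction was also negative for Mt2 (-3.28 ± 0.59), Prelp (-2.85 ± 0.44) and the natriuretic peptide clearance receptor Npr3 (-2.74 ± 0.52). It was positive for Rnf187 (2.94 ± 0.33), Inafm1 (2.60 ± 0.36), the splicing factor gene Lsm4 (2.51 ± 0.29) and the palmitoyltransferase gene Zdhhc7 (2.43 ± 0.34). Of 25 receptor targets, 5 had a negative interaction past the threshold and 0 a positive one (9 and 1 when adjusted over the list alone). They were Mt1 (-2.45 ± 0.50), Mt2, Cdkn1a (-2.41 ± 0.54), Fkbp5 (-2.21 ± 0.50) and Klf9, a transcription factor that the receptor induces (-1.51 ± 0.32; camera adjusted p = 0.00161, and adjusted p = 0.307 with an estimated correlation). Plin1 had a positive interaction (2.01 ± 0.33; lipolysis list camera adjusted p = 0.0352, and adjusted p = 0.467 with an estimated correlation). Rnf187, Inafm1 and Plin1 were also lower with cold in placebo and with corticosterone at 22 °C, against the same Ctrl_RT libraries. High Ctrl_RT levels alone would give all of these. Mitochondrially encoded and matrix lists were lower, lymphocyte and fatty acid oxidation lists higher (medians -1.84, -0.58, 0.90 and 0.45; camera adjusted p = 2.74e-14 to 0.00914, and adjusted p = 0.307 to 0.926 with an estimated correlation). edgeR called 66 positive and 27 negative interactions among 20175 genes (named ones at adjusted p = 0.000161 to 0.0481 by the quasi-likelihood test with Benjamini-Hochberg adjustment). The count was 13 without the 3 libraries rich in Crisp1, 159 without GC_RT replicate 1 and GC_CT replicate 1, 50 without GC_RT replicates 2 and 4, and 413 with DESeq2.

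**Figure D2:**
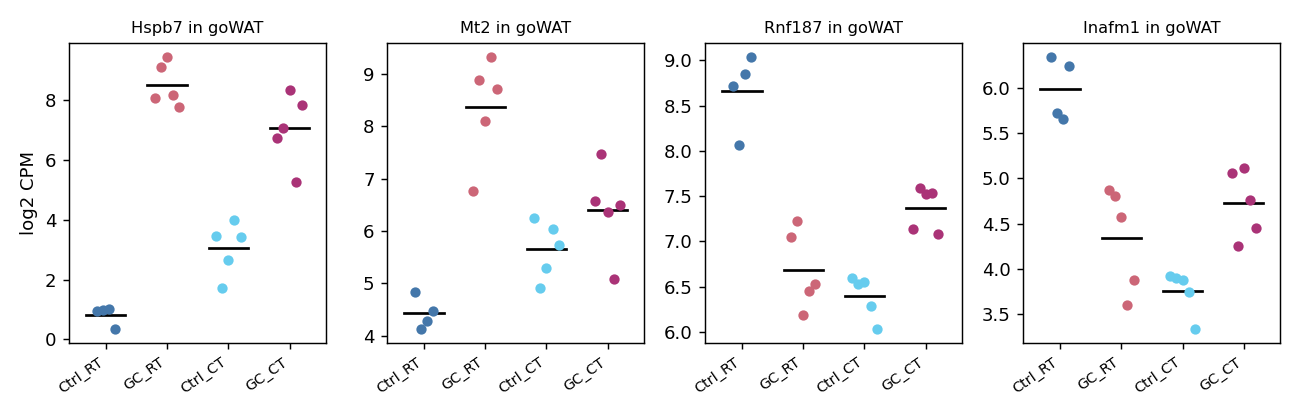
Log2 CPM of Hspb7, Mt2, Rnf187 and Inafm1 in each goWAT library by group, with points for libraries and bars for the group mean. Hspb7 and Mt2 stand highest in GC_RT, and Rnf187 and Inafm1 stand higher in Ctrl_RT than in the other groups.

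In scWAT at 22 °C, corticosterone (5 libraries against 4) lowered genes of heat production and fat synthesis. Of 20 thermogenic genes, 0 rose and 11 fell (1 and 15 when adjusted over the list alone): Dio2, the deiodinase that activates thyroid hormone, changed by -6.04 ± 1.16, Cox8b by -4.43 ± 0.51, Cidea, a lipid droplet gene of brown fat, by -4.04 ± 0.67, the elongase Elovl3 by -4.71 ± 0.90 and Ucp1 by -4.12 ± 1.004 (camera adjusted p = 1.73e-08, and adjusted p = 0.230 with an estimated correlation). Ucp1 stood at 126 ± 146 CPM in Ctrl_RT and 7.24 ± 6.82 in GC_RT. Of 21 lipogenesis genes, 0 rose and 13 fell (1 and 17 when adjusted over the list alone), with Elovl6 at -3.45 ± 0.49, Slc25a1 at -2.998 ± 0.38, fatty acid synthase (Fasn) at -1.97 ± 0.40 and the desaturase Scd1 at -1.79 ± 0.33 (camera adjusted p = 5.22e-14, and adjusted p = 0.230 with an estimated correlation). Of 32 nuclear-encoded oxidative phosphorylation genes, 0 rose and 9 fell (0 and 26 when adjusted over the list alone). Of 21 fatty acid oxidation genes, 1 rose and 10 fell (1 and 14 when adjusted over the list alone). Hadha fell (-1.69 ± 0.27) and Cpt1a, which takes fatty acids into mitochondria, rose by 1.04 ± 0.30 (camera adjusted p = 3.62e-15 and 7.59e-09, and adjusted p = 0.230 with an estimated correlation). Of 20 triglyceride genes, 0 rose and 6 fell (0 and 8 when adjusted over the list alone). Of 13 mitochondrially encoded ones, 0 rose and 2 fell (0 and 3 when adjusted over the list alone). For this pair of lists camera gave adjusted p = 1.01e-05 and 9.71e-05, and adjusted p = 0.230 to 0.430 with an estimated correlation. Of 18 lipolysis genes, 1 rose and 2 fell (1 and 3 when adjusted over the list alone), with G0s2 at 1.81 ± 0.34 (camera adjusted p = 0.00424, and adjusted p = 0.372 with an estimated correlation).

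Among the largest rises in the same comparison were Sfrp5 (4.72 ± 0.89), the imprinted gene Mest (4.69 ± 1.09), Thbs1, which encodes thrombospondin 1 (3.96 ± 0.58), Vgll3 (3.93 ± 0.59) and Lep (3.67 ± 0.50), while Aspg, an asparaginase gene, fell (-5.12 ± 0.61). Of 18 clock genes, 2 rose and 9 fell (3 and 11 when adjusted over the list alone), with Arntl at 3.59 ± 0.42 and Dbp at -4.75 ± 0.45 (camera adjusted p = 6.87e-05, and adjusted p = 0.230 with an estimated correlation). Of 18 macrophage markers, 3 rose and 0 fell (8 and 0 when adjusted over the list alone): the lysozyme gene Lyz2 by 2.86 ± 0.69 and the receptors Csf1r and Cd163 by 1.58 ± 0.46 and 1.38 ± 0.41 (camera adjusted p = 0.000145, and adjusted p = 0.490 with an estimated correlation). In the cell cycle list Ccnb1 rose by 3.15 ± 0.95, and 4 of 18 rose when adjusted over the list alone (camera adjusted p = 0.0191, and adjusted p = 0.703 with an estimated correlation). GC_RT replicates 2 and 3 carried the high macrophage and cell cycle levels given above, and without them the macrophage list had camera adjusted p = 0.858 and the cell cycle list, its direction turned, 0.0773. Of 28 matrix genes, 5 rose and 1 fell (9 and 2 when adjusted over the list alone), with Lox and Sparc at 2.21 ± 0.29 and 1.33 ± 0.27 (camera adjusted p = 0.00276, and adjusted p = 0.510 with an estimated correlation). Of 18 lymphocyte markers, 1 rose and 3 fell (1 and 5 when adjusted over the list alone): Cd8a and Igkc fell (-3.84 ± 1.17 and -3.94 ± 1.11) and Ighm rose by 3.13 ± 0.79, and erythrocyte genes were lower as a list (camera adjusted p = 0.00296 and 0.0382, and adjusted p = 0.430 to 0.611 with an estimated correlation). edgeR called 662 genes higher and 655 lower among 19003 tested (named genes at edgeR adjusted p = 4.03e-06 to 0.0497). Libraries did not overlap for 8.49% of tested genes (1.59% by chance). The count was 738 without GC_RT replicates 2 and 3, 636 with these groups alone, 2256 with DESeq2 and 2266 with limma and library weights.

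**Figure D3:**
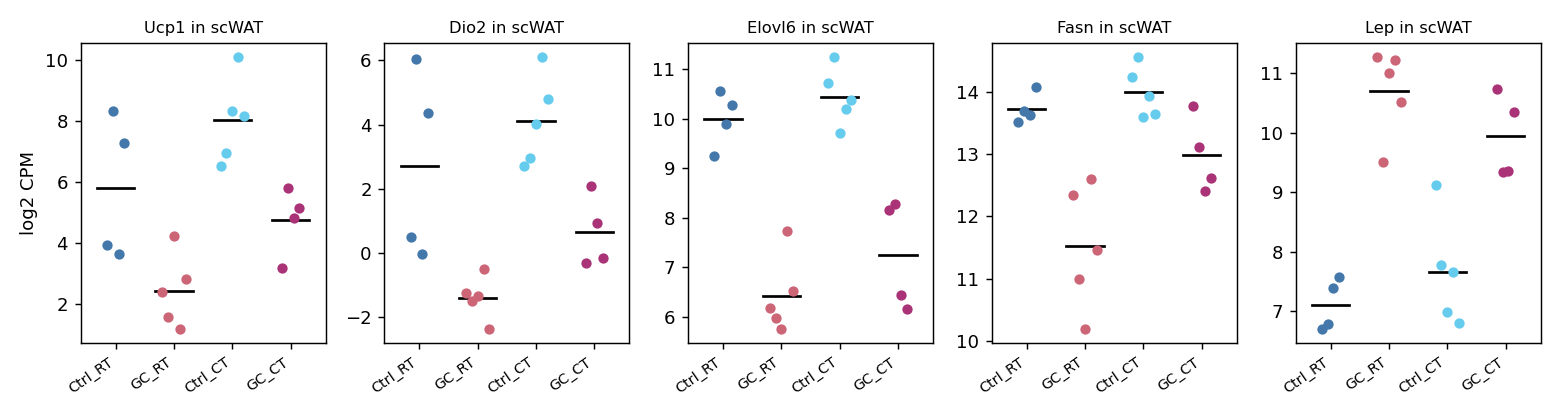
Log2 CPM of Ucp1, Dio2, Elovl6, Fasn and Lep in each scWAT library by group, with points for libraries and bars for the group mean. Elovl6 is lower and Lep higher in the corticosterone groups at both temperatures.

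At 13 °C in scWAT (4 GC_CT and 5 Ctrl_CT libraries), corticosterone raised Agt, the angiotensinogen gene, by 4.02 ± 0.83, and Lep by 2.14 ± 0.44. The imprinted genes Nnat, Plagl1 and Peg3 rose by 3.45 ± 0.44, 3.03 ± 0.39 and 3.02 ± 0.38. Irf4 (-3.84 ± 0.64), Aspg (-3.19 ± 0.58) and Usp2 (-2.92 ± 0.31) fell. Of 20 thermogenic genes, 0 rose and 6 fell (1 and 15 when adjusted over the list alone), with Cox7a1 at -3.05 ± 0.55, Cidea at -2.87 ± 0.68 and Cox8b at -2.65 ± 0.50, while Ucp1 (-3.58 ± 1.05) did not pass (edgeR adjusted p = 0.0808). Of 32 oxidative phosphorylation genes, 0 rose and 6 fell (0 and 23 when adjusted over the list alone), with Cox5a at -1.45 ± 0.33. Of 21 lipogenesis genes, 0 rose and 6 fell (0 and 10 when adjusted over the list alone), with Elovl6 at -2.98 ± 0.51 and Slc25a1 at -2.11 ± 0.39. Of 21 fatty acid oxidation genes, 0 rose and 3 fell (0 and 11 when adjusted over the list alone), with Acadl at -1.86 ± 0.33. Of 20 triglyceride genes, 0 rose and 2 fell (1 and 5 when adjusted over the list alone), with Lpin1 at -1.31 ± 0.31. For these 5 lists camera gave adjusted p = 5.09e-19 to 4.03e-06, and adjusted p = 0.122 to 0.169 with an estimated correlation. Of 16 white adipocyte genes, 4 rose and 0 fell (7 and 0 when adjusted over the list alone): besides Agt and Lep, Npr3 rose by 1.82 ± 0.37 (camera adjusted p = 6.96e-06, and adjusted p = 0.122 with an estimated correlation).

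Of 24 receptor targets in this comparison, 1 rose and 5 fell (3 and 9 when adjusted over the list alone): Per1, Sgk1 and Nfkbia fell (-2.52 ± 0.35, -1.85 ± 0.25 and -1.54 ± 0.25) and the sulfotransferase gene Sult1a1 rose by 1.10 ± 0.26 (camera adjusted p = 6.96e-06, and adjusted p = 0.114 with an estimated correlation). Of 18 clock genes, 2 rose and 7 fell (4 and 9 when adjusted over the list alone), with Arntl at 3.68 ± 0.40 and Dbp at -4.10 ± 0.47 (camera adjusted p = 0.000241, and adjusted p = 0.125 with an estimated correlation). Camera placed the mitochondrially encoded, cell cycle, lymphocyte and erythrocyte lists lower and skeletal muscle genes higher (adjusted p = 0.00322 to 0.0188, and adjusted p = 0.611 to 0.677 with an estimated correlation). edgeR called 276 genes higher and 217 lower among 19003 tested (named genes at edgeR adjusted p = 4.11e-05 to 0.0276). Libraries did not overlap for 8.53% of tested genes (1.59% by chance). The count was 36 without the 4 keratin-rich libraries, which left 1 GC_CT library, 290 without the libraries rich in muscle transcripts, 911 with these groups alone and 1111 with DESeq2.

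Placebo scWAT at 13 °C against 22 °C (5 and 4 libraries) gave list shifts but no single gene. The thermogenic list had a median log2 fold change of 0.65 (1 of 20 rose when adjusted over the list alone), the fatty acid oxidation list of 0.58, the lipogenesis list of 0.44 and the receptor targets of 0.42 (camera adjusted p = 6.48e-06 to 0.0178, and adjusted p = 0.553 to 0.666 with an estimated correlation). Ucp1 stood at 388 ± 414 CPM in Ctrl_CT and 126 ± 146 in Ctrl_RT (1.62 ± 0.96, edgeR adjusted p = 0.490). Macrophage, matrix, progenitor, white adipocyte and erythrocyte genes were lower as lists (medians -1.23, -0.60, -0.42, -0.34 and -0.97; camera adjusted p = 3.18e-05 to 0.0415, and adjusted p = 0.553 to 0.666 with an estimated correlation). Adjusted over the list alone, 3 of 18 macrophage markers fell. edgeR called 0 of 19003 genes, with 2364 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0582, DESeq2 called 182 and limma with library weights 776. Without Ctrl_CT replicate 5, the library of low quality, edgeR called 37.

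Under corticosterone, scWAT at 13 °C against 22 °C (4 and 5 libraries) differed in macrophage and dividing-cell genes. Of 18 macrophage markers, 0 rose and 14 fell (0 and 16 when adjusted over the list alone): the lysosomal glycoprotein gene Gpnmb changed by -6.03 ± 1.28, cathepsin S (Ctss) by -4.49 ± 1.02, Cd68 by -3.85 ± 0.90 and Lyz2 by -3.37 ± 0.71 (camera adjusted p = 1.32e-09, and adjusted p = 0.513 with an estimated correlation). Of 18 cell cycle genes, 0 rose and 11 fell (0 and 16 when adjusted over the list alone), with the proliferation marker Mki67 at -5.56 ± 1.23 and the mitotic kinase Aurkb at -5.17 ± 1.15 (camera adjusted p = 1.88e-05, and adjusted p = 0.513 with an estimated correlation). Gpnmb stood at 983 and 589.6 CPM in GC_RT replicates 2 and 3, at 23.6, 13.97 and 171 in replicates 1, 4 and 5, and at 5.44 ± 1.35 in GC_CT (mean ± SD). Of 28 matrix genes, 0 rose and 9 fell (1 and 18 when adjusted over the list alone), with the collagen genes Col6a1 and Col15a1 at -1.60 ± 0.34 and -2.10 ± 0.44. Of 16 progenitor markers, 0 rose and 3 fell (0 and 4 when adjusted over the list alone). For this pair of lists camera gave adjusted p = 8.76e-09 and 0.0328, and adjusted p = 0.513 with an estimated correlation. Of 21 lipogenesis genes, 6 rose and 0 fell (10 and 0 when adjusted over the list alone), with Scd1 at 2.15 ± 0.34 and Fasn at 1.31 ± 0.40 (camera adjusted p = 5.61e-06, and adjusted p = 0.513 with an estimated correlation). Of 20 thermogenic genes, 4 rose and 0 fell (7 and 0 when adjusted over the list alone), with Cox8b at 1.74 ± 0.46 and the proton channel Otop1 at 2.94 ± 0.79. Of 21 oxidation genes, 5 rose and 0 fell (9 and 1 when adjusted over the list alone). Of 18 lipolysis genes, 4 rose and 0 fell (7 and 0 when adjusted over the list alone), with the beta-3 adrenoceptor Adrb3 at 1.98 ± 0.46. Camera gave these 3 lists adjusted p = 0.000117 to 0.0221, and adjusted p = 0.513 with an estimated correlation. Of 20 triglyceride genes, 3 rose and 2 fell (3 and 2 when adjusted over the list alone). Of 18 clock genes, 2 rose and 0 fell (2 and 0 when adjusted over the list alone), and both lists were higher by camera (adjusted p = 0.0328 and 0.0298, and adjusted p = 0.513 with an estimated correlation). Outside the lists, Bckdha, of branched-chain amino acid breakdown, rose by 2.67 ± 0.77 and Aspg by 2.65 ± 0.56.

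For this comparison edgeR called 573 genes higher and 982 lower among 19003 tested (named genes at edgeR adjusted p = 0.0122 to 0.0455). The groups did not overlap for 8.67% of tested genes (1.59% by chance). It called 2 genes without GC_RT replicates 2 and 3, 4 without the 4 keratin-rich libraries, 69 without GC_CT replicate 3 and 3645 without GC_RT replicate 1, and 376 with these groups alone in the fit.

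**Figure D4:**
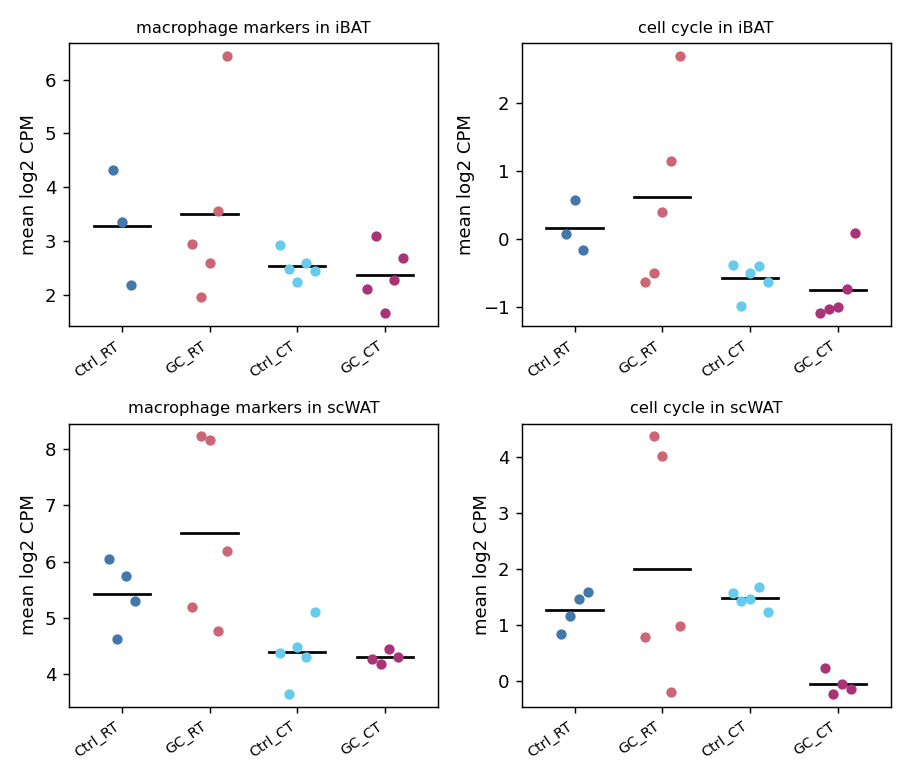
Mean log2 CPM of 18 macrophage markers and of the cell cycle genes in each iBAT and scWAT library, by group, with points for libraries and bars for the group mean. GC_RT replicates 2 and 3 of scWAT and GC_RT replicate 5 of iBAT stand above the other libraries of their depots on both lists.

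The interaction in scWAT (18 libraries) called no gene. Medians were negative for cell cycle genes (-3.77, 12 of 18 negative when adjusted over the list alone), macrophage markers (-1.73), receptor targets (-0.36, 6 of 24 adjusted over the list alone) and matrix genes (-0.25). White adipocyte (0.65) and lipogenesis (0.47) lists were positive. Without GC_RT replicates 2 and 3 the cell cycle and macrophage medians were -0.95 and -0.32, with camera adjusted p = 0.00863 and, in the other direction, 0.943. Camera gave these 6 lists adjusted p = 1.29e-06 to 0.0141, and adjusted p = 0.333 to 0.927 with an estimated correlation. edgeR called 0 of 19003 genes, with 1838 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0824, DESeq2 called 154 and limma with library weights 7.

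Differences between depots in the corticosterone effect were tested for each gene in 1 fit over the 55 libraries (edgeR's quasi-likelihood F-test with Benjamini-Hochberg adjustment). At 22 °C, Mylk, the myosin light chain kinase gene, had log2 fold changes of -0.38 in iBAT, 2.60 in goWAT and 1.27 in scWAT, adjusted p = 0.000338. The metallothionein Mt1 had -0.55 in iBAT, 3.40 in goWAT and 1.38 in scWAT, adjusted p = 0.00832. Dio2 had -0.60 in iBAT, 4.01 in goWAT and -6.02 in scWAT, adjusted p = 0.0163, and in goWAT it stood at 26.3 CPM in GC_RT replicate 1, the library rich in brown fat transcripts, and at 0.190 to 2.51 in the other 4. Timp4, an inhibitor of matrix proteases, had -0.19 in iBAT, 2.65 in goWAT and 3.42 in scWAT, adjusted p = 0.000338, and Lpl, the lipoprotein lipase, -1.49 in iBAT, 0.10 in goWAT and 0.34 in scWAT, adjusted p = 0.0240. At 13 °C, the amino acid transporter Slc7a8 had -2.68 in iBAT, 1.18 in goWAT and 1.90 in scWAT, adjusted p = 4.23e-05, and Rasd1 -2.75 in iBAT, 1.89 in goWAT and 2.04 in scWAT, adjusted p = 0.000141. The test called 165 genes at 22 °C and 52 at 13 °C of 22245, with 3810 and 2737 at an unadjusted p under 0.05. Without libraries of low quality the counts were 61 and 47, and with DESeq2 763 and 273. Leaving out 1 library moved the counts to between 8 (without iBAT Ctrl_RT replicate 1) and 384 (without goWAT GC_RT replicate 1) at 22 °C and between 17 (without scWAT GC_CT replicate 4) and 92 (without iBAT GC_CT replicate 2) at 13 °C.

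Some genes were called with corticosterone in several depots. At 22 °C, 17 genes rose and 26 fell in all 3 depots, among them Arntl, Lox and Tnfrsf12a up and Irf4, Klf15, Dbp and Nfkbia down. At 13 °C the numbers were 12 and 18, with Arntl, Npas2 and Lox up and Irf4, Sgk1, Usp2 and Dbp down. In goWAT and scWAT at 22 °C, 226 genes rose and 164 fell in both (independent lists would share 21.7 and 19.2), and 0 genes were called in opposite directions. In goWAT and scWAT at 13 °C, 52 genes rose and 36 fell in both (independent lists would share 2.50 and 1.37). Between temperatures, where the compared groups shared no library, 19 genes rose and 24 fell at both in iBAT, 73 and 54 in goWAT (6 in opposite directions) and 142 and 141 in scWAT. Independent lists would share 0.183 and 0.232, 5.36 and 3.44, and 9.61 and 7.48. Libraries of different depots that come from 1 animal would raise the overlap between depots.

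**Figure D5:**
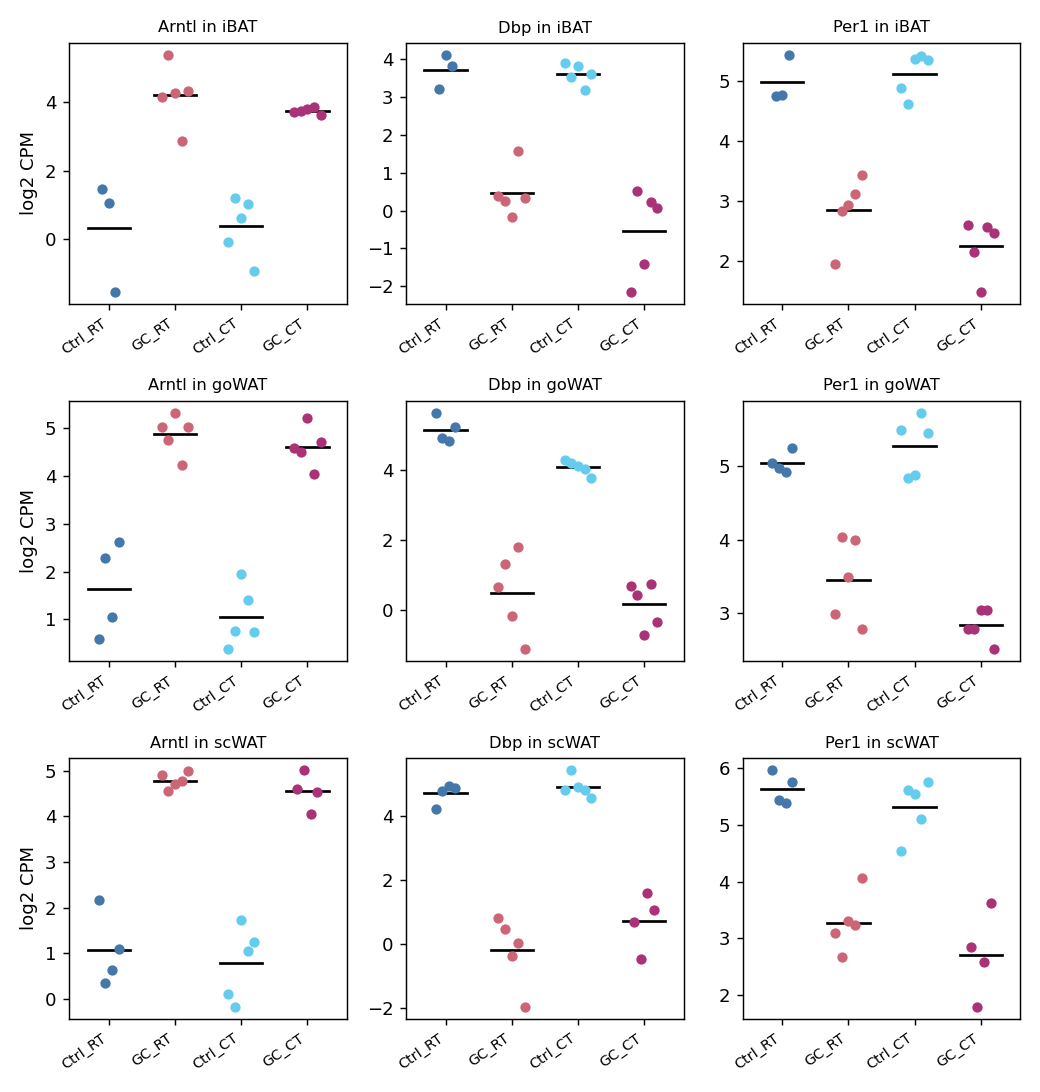
Log2 CPM of Arntl, Dbp and Per1 in each library by group and depot, with points for libraries and bars for the group mean. In every depot and at both temperatures, mean Arntl is higher and mean Dbp and Per1 are lower with corticosterone than with placebo.

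Over all 15 comparisons within a depot, camera called 122 of 370 list tests with its preset correlation. With an estimated correlation 2 held, the circadian clock list with corticosterone at 13 °C in iBAT and in goWAT. The lists for creatine and calcium cycling, insulin signalling and glucose uptake, inflammatory mediators, and smooth muscle and pericyte markers were called in none of the comparisons, and too few epididymis markers were measured for a test.

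Positions of 5 genes named above are on GRCm38 (the mm10 assembly), with the annotation's biotype. They were Arntl (ENSMUSG00000055116, protein coding, chromosome 7, 113207465 to 113314126), Dbp (ENSMUSG00000059824, protein coding, chromosome 7, 45705088 to 45710203), Irf4 (ENSMUSG00000021356, protein coding, chromosome 13, 30749226 to 30766976), Lep (ENSMUSG00000059201, protein coding, chromosome 6, 29060220 to 29073877) and Ucp1 (ENSMUSG00000031710, protein coding, chromosome 8, 83290352 to 83298452).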

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

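Tests chosen only after the result was seen were those of collection time, of other tissue in single depots, of macrophages, lymph node, library size and epididymis, and the other splits of the 4 comparisons between groups in iBAT. A single library stood far from the rest of its group, by Dixon's ratio of gap to range, for 29 of 480 groups of values (6.04%), and chance sets apart about 1 in 20. For skeletal muscle markers the highest mean log2 CPM stood at 3.60 in iBAT GC_RT replicate 3, 5.52 in goWAT GC_RT replicate 2, 5.42 in scWAT Ctrl_RT replicate 1, 7.27 in scWAT GC_RT replicate 2 and 3.32 in scWAT Ctrl_CT replicate 1. For thermogenic genes it stood at 6.38 in iBAT GC_RT replicate 2 and 5.30 in goWAT GC_CT replicate 1. For lymphocyte markers it stood at 0.99 in iBAT GC_RT replicate 5 and 0.13 in iBAT Ctrl_CT replicate 3. The lowest lymphocyte mean stood at -0.95 in scWAT GC_CT replicate 5. Of single genes, 19 of 373 groups held such a library. In iBAT, the high values in CPM were Gpat4 at 244 in GC_CT replicate 3, and the low ones were Sgk1 at 73.7 in Ctrl_CT replicate 1 and Usp2 at 72.7 in Ctrl_CT replicate 1. In goWAT, the high values in CPM were Dusp10 at 63.8 in GC_CT replicate 1, Fkbp5 at 64.8 in Ctrl_RT replicate 3, Irf4 at 86.7 in Ctrl_RT replicate 4, Mthfd2 at 292 in GC_CT replicate 3, Nrg4 at 68.3 in GC_RT replicate 4 and Slc7a8 at 26.9 in Ctrl_CT replicate 3, and the low ones were Hspb7 at 1.22 in Ctrl_RT replicate 4 and Lsm4 at 31.7 in GC_CT replicate 1. In scWAT, the high values in CPM were Ighm at 47.9 in Ctrl_RT replicate 1, and the low ones were Adrb3 at 33.4 in GC_RT replicate 3, Cfd at 26579 in Ctrl_RT replicate 2, Cfd at 1429 in GC_RT replicate 3, Nrg4 at 123 in Ctrl_CT replicate 2, Plagl1 at 0.925 in Ctrl_CT replicate 5, Scd1 at 29676 in GC_CT replicate 5 and Slc25a1 at 2206 in Ctrl_RT replicate 1.

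The corticosterone effect was tested for a difference between groups, and these results passed. The interaction with temperature called 93 genes in goWAT by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with log2 values, as named above, of -2.41 for Cdkn1a, -2.21 for Fkbp5, -3.70 for Hspb7, 2.60 for Inafm1, -1.51 for Klf9, 2.51 for Lsm4, -2.45 for Mt1, -3.28 for Mt2, -2.74 for Npr3, 2.01 for Plin1, -2.85 for Prelp, 2.94 for Rnf187 and 2.43 for Zdhhc7. As lists by camera, with adjusted p in parentheses, the interaction was called in goWAT for extracellular matrix (0.000120), fatty acid oxidation (0.00914), glucocorticoid receptor targets (0.00161), lipolysis (0.0352), lymphocyte markers (0.00694) and mitochondrially encoded transcripts (2.74e-14), in iBAT for Schwann cell and nerve markers (0.00732), circadian clock (0.00845), erythrocyte markers (0.00723), fatty acid oxidation (0.00723), skeletal muscle markers (1.47e-06) and white adipocyte identity (0.00255), and in scWAT for cell cycle (1.29e-06), de novo lipogenesis (0.0141), extracellular matrix (0.0126), glucocorticoid receptor targets (0.000806), macrophage markers (0.00127) and white adipocyte identity (0.00111), none of which held with an estimated correlation, and the macrophage list in scWAT turned its direction by camera without GC_RT replicates 2 and 3. The test between depots, for which chance cannot be excluded (below), called 165 genes at 22 °C and 52 at 13 °C. Among them, with adjusted p by edgeR's quasi-likelihood F-test with Benjamini-Hochberg adjustment, were Dio2 (0.0163), Lpl (0.0240), Mt1 (0.00832), Mylk (0.000338) and Timp4 (0.000338) at 22 °C and Rasd1 (0.000141) and Slc7a8 (4.23e-05) at 13 °C.

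Circadian clock genes moved with corticosterone in all 3 depots, with 8 to 11 of 18 called in each comparison. Libraries that hold other tissue or cells are argued against as the whole cause in iBAT, goWAT and scWAT at 22 °C, since with any such set left out at least 75%, 81.8% and 90.9% of the called clock genes still passed. In scWAT at 13 °C, 88.9% passed without muscle-rich libraries, but 2 of 9 (22.2%) without the 4 keratin-rich ones: all 9 kept their direction, with a median size of 2.80 ± 0.398 log2 before and 2.48 ± 0.651 after (± SE), and 7 calls ended as 1 GC_CT library was left, so the effect and keratin-rich tissue cannot be told apart there. A different time of collection for treated mice may give the same shift, and as the labels give no times and Arntl rose while Dbp fell in 6 of 6 comparisons, time and treatment cannot be told apart. An action of corticosterone on the clock, which the design names, stays open and untested.

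Macrophage and cell cycle genes were lower in corticosterone-treated scWAT at 13 °C than at 22 °C. A lymph node in the captured area is argued against, since the higher of the 2 mean lymphocyte levels in GC_RT replicates 2 and 3 lay at -0.63 log2 CPM relative to the median of the other 16 scWAT libraries (Cd74 at 252 and 279.8 CPM, Igkc at 0.603 and 0.0873, and 0 of the 18 markers in another list), and so is library size, at 1.19 times the mean of the other 3 (totals of 43758510 and 27797803 against 43101668, 20841288 and 26564850 counts). Macrophages in the areas of this pair are a candidate source, which leaving the pair out cannot decide, since it was picked for its macrophage level: 2 genes were called without it, 114 to 4013 without each of the other 9 pairs, 4 without the keratin-rich libraries and 69 without GC_CT replicate 3. Among the 18 macrophage markers, all measured in scWAT and 1 (Lpl) also in another list, Lyz2 stood at 7521 and 4169.5 CPM in the pair and Gpnmb at 983 and 589.6. Whether treatment at 22 °C brought these cells to some areas, or the choice of areas did, stays open and untested.

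Placebo goWAT had 59 genes lower at 13 °C than at 22 °C, among them Plin1 and Rnf187. GC content and transcript length are argued against as the whole cause: with a trend over GC content removed 91.5% of these genes stayed past the threshold (median log2 fold change -1.61 before and -1.47 after), though their median GC content was 53.95% against 49.3% of all tested genes, and with a trend over length 86.4% did (-1.54 after). Of 13 epididymis markers, 11 were in the counts, Crisp1 the most abundant. Without the 3 libraries rich in Crisp1 the median of the fallen genes was -1.55, and the count 12 with fewer libraries. As the genes were picked in the same libraries, this cannot decide on epididymis in the captured area. The count rests in part on 1 library, at 11 without Ctrl_RT replicate 4. A response to the temperature, which the design names, and a deviation of the Ctrl_RT libraries stay open and untested.

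Other splits of the same libraries into groups of the same sizes show how many called genes an arbitrary grouping gives. In parentheses stand the real count, the number of splits with as many genes (the real one included), the number of splits fitted and the highest count of another split. Chance can be excluded for the following, with shares of such splits under 0.05 (uncorrected, libraries taken as independent). In iBAT they were corticosterone at 22 °C (114, 1, 56 and 44) and 13 °C (125, 1, 100 and 2). In goWAT they were corticosterone at 22 °C (1206, 2, 100 and 1755) and 13 °C (292, 1, 100 and 2). Also in goWAT were cold under placebo (63, 1, 100 and 1) and the interaction (93, 3, 100 and 361). In scWAT they were corticosterone at 22 °C (1317, 3, 100 and 2241) and 13 °C (493, 1, 100 and 102). The last was cold under corticosterone in scWAT (1555, 2, 100 and 3966). Where another split called more genes than the real one, this rests on the share alone. The iBAT count of 3 was 0 with a replicate block, the groups alone or without Ctrl_RT replicate 1 or 2. With shares of 0.05 or more, chance is also not excluded for cold under corticosterone in goWAT (3, 13, 100 and 735), the depot test at 22 °C (165, 5, 40 and 361) and the depot test at 13 °C (52, 2, 40 and 253). For the interaction in iBAT (0, 100, 100 and 71), cold under placebo in scWAT (0, 100, 100 and 82) and the interaction in scWAT (0, 100, 100 and 109) every split reaches 0, so the splits decide nothing. Another split called over 2 times the real count for both depot tests, the goWAT interaction, cold under placebo in iBAT and cold under corticosterone in goWAT and scWAT. What sets the libraries of such splits apart was not tested.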

How the results depend on the processing

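Fits without libraries rich in other tissue, the repeats of the list tests and the depot tests without each library were chosen after seeing the data. Of 176 calls of named genes, none changed direction in 1483 refits under other settings, and 1243 of these refits kept the call, as did 1576 of 1857 with 1 library left out. RLE scaling, no filter, DESeq2, library weights and a replicate block kept 174, 154, 176, 168 and 135 of the 176. Without muscle-rich, macrophage-rich, brown-fat-rich, Crisp1-rich and low-quality libraries 110 of 145, 32 of 65, 54 of 57, 45 of 64 and 56 of 71 were kept. Camera calls kept in 857 of 1160 refits and 1132 of 1266 with 1 library left out, but of 122 list calls 2 held with an estimated correlation and 25 with fry. Counts of called genes were less stable, within 1.5 times in 55 of 140 refits and 127 of 220 with 1 library left out. In the order corticosterone at 22 °C, at 13 °C, cold under placebo, cold under corticosterone and interaction, DESeq2 called 394, 385, 78, 388 and 9 in iBAT, 2204, 897, 196, 418 and 413 in goWAT, 2256, 1111, 182, 2784 and 154 in scWAT and 763 and 273 between depots. Limma with library weights called 971, 263, 1029, 4 and 1 in iBAT, 1019, 2202, 186, 21 and 189 in goWAT, 2266, 1514, 776, 2891 and 7 in scWAT and 1299 and 447 between depots. With the compared groups alone, which gives no other fit for the interaction, the counts were 65, 156, 0 and 1 in iBAT, 655, 500, 113 and 0 in goWAT, 636, 911, 26 and 376 in scWAT and 92 and 98 between depots. Otherwise the count moved by over 1.5 times with RLE to 1 for cold under placebo in scWAT. With no filter it moved to 3 for cold under corticosterone in iBAT, 1 for cold under corticosterone in goWAT, 5 for cold under placebo in scWAT and 107 for the depot test at 22 °C. Without low-quality libraries, of which iBAT had none, it moved to 709, 0 and 50 in goWAT, 37 in scWAT and 61 between depots (above). Without muscle-rich libraries it moved to 54 for corticosterone at 13 °C in iBAT, 0 for cold under placebo in iBAT, 1 for cold under corticosterone in goWAT, 290 for corticosterone at 13 °C in scWAT and 494 for cold under corticosterone in scWAT. Without macrophage-rich ones it moved to 26 and 0 in iBAT and 738 and 2 in scWAT, as given above. Without mesothelium-rich libraries it moved to 36 for corticosterone at 13 °C in scWAT, 4 for cold under corticosterone in scWAT and 1 for the interaction in scWAT. Without brown-fat-rich ones it moved in goWAT to 441 for corticosterone at 13 °C, 0 for cold under corticosterone, and 2113 and 159 (above). Without those rich in Crisp1 it moved in goWAT to 1 for cold under corticosterone and to 91, 12 and 13 as given above. Directions turned for 3 results: without macrophage-rich libraries for macrophage markers in the scWAT interaction (camera adjusted p = 0.943) and cell cycle genes with corticosterone at 22 °C in scWAT (adjusted p = 0.0773), and for Ucp1 with corticosterone at 22 °C in iBAT, which did not pass (log2 fold change 0.40 with library weights, 0.59 without muscle-rich libraries, and with 1 library left out -1.22 without Ctrl_RT replicate 2 to 0.58 without Ctrl_RT replicate 3). Of 15 named results that did not pass, 5 passed in a refit. With DESeq2 and library weights these were Ucp1 with corticosterone at 13 °C in scWAT, Hsd11b1 at 13 °C in iBAT and Nrg4 and Cfd at 22 °C in iBAT. With the groups alone Hsd11b1 and this Cfd result passed, without muscle-rich libraries or without iBAT Ctrl_RT replicate 3 Nrg4 and Cfd, and without GC_RT replicate 4 Nrg4. Cfd at 22 °C in goWAT passed without muscle-rich libraries, those of low quality or GC_RT replicate 2. Fits without some libraries rest on fewer samples, and apart from that the cause was not tested.

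Leaving out 1 library at a time, 114 of 176 named calls were kept in every refit. The libraries that moved a count by over 1.5 times are given by group and replicate number, with the count without them, and a group left with 1 or 2 libraries borrows its spread from the others. Corticosterone at 22 °C in iBAT ranged from 42 to 188, where omitting Ctrl_RT 1, 2 and 3 gave 42, 59 and 188 and GC_RT 1 and 2 gave 55 and 74. Lrrc32, Lum and Tnfrsf12a lost the call. Corticosterone at 13 °C in iBAT ranged from 64 to 107, where omitting Ctrl_CT 2, 3 and 4 gave 74, 75 and 68 and GC_CT 4 and 5 gave 80 and 64. Gpat4, Nrg4 and Phlda1 lost the call. Cold under placebo in iBAT ranged from 0 to 3, where omitting Ctrl_RT 1, 2 and 3 gave 0, 0 and 1 and Ctrl_CT 2 and 3 gave 1 and 1. BC028528, Cyp2b10 and Retreg1 lost the call. Cold under corticosterone in iBAT ranged from 1 to 9, where omitting GC_RT 1, 3 and 4 gave 2, 2 and 9 and GC_CT 4 and 5 gave 3 and 5. The interaction in iBAT ranged from 0 to 1, where omitting GC_CT 1 gave 1. Corticosterone at 22 °C in goWAT ranged from 567 to 1973, where omitting Ctrl_RT 2, 3 and 4 gave 803, 703 and 567 and GC_RT 1 gave 1973. Cd4, G0s2, Irf4, Kdr and Slc25a1 lost the call. Corticosterone at 13 °C in goWAT ranged from 117 to 377, where omitting Ctrl_CT 1, 3, 4 and 5 gave 165, 149, 135 and 117 and GC_CT 3, 4 and 5 gave 140, 181 and 134. Abcg2, Cdh5, Gpihbp1, Irf4, Lep and Rrm2 lost the call. Cold under placebo in goWAT ranged from 11 to 84, where omitting Ctrl_RT 4 gave 11 and Ctrl_CT 4 and 5 gave 29 and 34. Adcyap1r1 and Trim14 lost the call. Cold under corticosterone in goWAT ranged from 0 to 304, where omitting GC_RT 1, 2, 3, 4 and 5 gave 304, 1, 36, 0 and 35 and GC_CT 2, 3, 4 and 5 gave 5, 0, 0 and 1. Prelp and mt-Ts1 lost the call. The interaction in goWAT ranged from 35 to 180, where omitting Ctrl_RT 1 and 4 gave 54 and 35, GC_RT 1 gave 180, Ctrl_CT 1, 4 and 5 gave 49, 54 and 50 and GC_CT 2, 3, 4 and 5 gave 149, 50, 53 and 60. Cdkn1a, Fkbp5, Hspb7, Klf9, Mt1 and Npr3 lost the call. Corticosterone at 22 °C in scWAT ranged from 709 to 2033, where omitting Ctrl_RT 2 and 4 gave 709 and 716 and GC_RT 1 and 3 gave 2033 and 873. Ccnb1, Cd163, Cd8a, Cpt1a, Csf1r, Ighm, Igkc, Lyz2, Mest and Ucp1 lost the call. Corticosterone at 13 °C in scWAT ranged from 292 to 462, where omitting Ctrl_CT 4 gave 294 and GC_CT 4 gave 292. Agt, Cidea, Cox5a, Lpin1 and Sult1a1 lost the call. Cold under placebo in scWAT ranged from 0 to 37, where omitting Ctrl_RT 4 gave 3 and Ctrl_CT 5 gave 37. Cold under corticosterone in scWAT ranged from 69 to 3645, where omitting GC_RT 1, 2 and 3 gave 3645, 845 and 425 and GC_CT 1, 3 and 4 gave 805, 69 and 287. Adrb3, Aspg, Aurkb, Bckdha, Cd68, Col15a1, Col6a1, Cox8b, Ctss, Fasn, Gpnmb, Lyz2, Mki67 and Otop1 lost the call. The interaction in scWAT ranged from 0 to 13, where omitting GC_RT 4 gave 1, Ctrl_CT 3 gave 3 and GC_CT 1 and 5 gave 1 and 13. The depot test at 22 °C ranged from 8 to 384, where omitting iBAT Ctrl_RT 1, 2 and 3 gave 8, 43 and 351, iBAT GC_RT 1, 2 and 5 gave 67, 47 and 276, goWAT Ctrl_RT 2, 3 and 4 gave 89, 108 and 58, goWAT GC_RT 1 and 4 gave 384 and 100 and scWAT Ctrl_RT 2 gave 97. Dio2, Lpl and Mt1 lost the call. The depot test at 13 °C ranged from 17 to 92, where omitting iBAT GC_CT 1, 2 and 4 gave 34, 92 and 30, goWAT Ctrl_CT 1 and 4 gave 32 and 33, scWAT Ctrl_CT 2 and 4 gave 26 and 28 and scWAT GC_CT 3 and 4 gave 21 and 17. Calls of lists lay at 116 to 132 of 370. With a replicate block the counts were, in the order above, 98, 120, 0, 4 and 0 in iBAT, 843, 145, 23, 0 and 35 in goWAT, 910, 286, 0, 494 and 0 in scWAT and 70 and 86 between depots. Within a depot, deviations from the group means of libraries with the same number had median correlations of -0.00261 to 0.0110. Between depots, the same group and number gave medians of 0.0190 to 0.0763, and other numbers of the group -0.0225 to -0.0171. Pairs ran from -0.1975 to 0.440, so shared animals between depots are not excluded. Settings that leave libraries out give a value only where the compared groups hold such libraries, and camera was not run with DESeq2. Depth limits genes of low count, which the filter removed, and the spread between libraries limits the rest.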

Other observations

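Nrg4 and Cfd were chosen after their values were seen. Nrg4, the gene of neuregulin 4, was lower in each depot. In scWAT it went from 173 to 33.2 CPM at 22 °C (-2.38 ± 0.29, 5 libraries against 4) and from 184 to 50.6 at 13 °C (-1.86 ± 0.30). It fell in goWAT at 22 °C (-1.69 ± 0.36) and 13 °C (-1.76 ± 0.35) and in iBAT at 13 °C (-1.41 ± 0.29), with adjusted p = 4.35e-05 to 0.0246 over these 5 comparisons by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. In iBAT at 22 °C the log2 fold change was -1.24 ± 0.33 (edgeR adjusted p = 0.0868). Cfd, the gene of adipsin, fell in scWAT at 22 °C, with 26579 to 33278 CPM in Ctrl_RT libraries and 1429 to 8469 in GC_RT (-2.43 ± 0.39, edgeR adjusted p = 0.000500). At 13 °C it stood at 9792 to 20271 CPM in Ctrl_CT and 12987 to 26923 in GC_CT, and the interaction did not pass (edgeR adjusted p = 0.157). At 22 and 13 °C it did not pass in iBAT (-4.02 ± 0.94 and -1.18 ± 0.80) or goWAT (-1.16 ± 0.57 and -0.27 ± 0.54, edgeR adjusted p = 0.0564 to 0.865 over these 4).

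The machinery that reads corticosterone was expressed in each depot. Nr3c1, the glucocorticoid receptor gene, had group means of 45.3 to 66.8 CPM in iBAT, 99.995 to 116 in goWAT and 89.3 to 161 in scWAT. Hsd11b1, whose enzyme regenerates active glucocorticoid inside the cell, had positive log2 fold changes with corticosterone in all 6 comparisons, from 0.38 (scWAT at 22 °C) to 1.68 (iBAT at 13 °C), and passed in none of them (adjusted p = 0.122 to 0.608 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).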
